A study of Homo sapiens with 6 samples.

How the data were processed

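RNA was measured by sequencing after RNA immunoprecipitation (RIP-seq) from the free 40S fraction of HCT116 cells, with 2 LARP1 immunoprecipitates, 2 control immunoprecipitates made with normal rabbit serum IgG and 2 Input libraries. Per the labels' protocols, RNA was purified with TRIzol and libraries were made with a stranded mRNA kit without poly(A) selection, so RNA without a poly(A) tail could enter every library. Groups were taken from the sample titles, which number the libraries of a group as replicates. No source used here says that they came from separate cultures, so p-values measure the spread between these libraries.

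The deposited values are raw read counts per gene from the authors, 1 file per library, with no normalization and no pooling. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie2, TopHat2 2.1.1, featureCounts and Subread 1.20.6, with the genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies, of overlapping genes and of antisense genes may therefore be shared between IDs, which could not be assessed here. Each file lists 60554 versioned Ensembl gene IDs. Of these, 36322 had no count in any library. Of 50 IDs with the ENSGR prefix, which marks second copies of genes, 1 had a count.

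The files do not pair the IDs with gene symbols, and 0 of the IDs matched the gene table used here (NCBI RefSeq, GRCh38.p14), whose Ensembl column was empty. No gene symbol, gene type, gene length or coordinate is therefore reported. The gene lists fixed before the data were examined were not applied, and the tests planned on them were not run. The planned rule for named genes also asked for a symbol. It was applied without the symbol and gene type conditions: genes past the threshold, with a mean of at least 10 CPM (counts scaled to library size) in the higher group and no overlap between the libraries of the groups, ordered by log2 fold change. The first 2 higher and first 2 lower IDs in the LARP1 IP against the IgG IP are printed, and the first 10 in each direction are summarised.

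Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 10788 genes holding 99.69% to 99.85% of each library's counts. Libraries were scaled by TMM. All 6 libraries entered a single quasi-likelihood fit (estimateDisp, glmQLFit and glmQLFTest) with the group as the only term and 3 residual degrees of freedom, because 2 libraries per group give a poor estimate of the spread. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each comparison. Fold changes are edgeR's, with a prior count of 0.125, and the standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. CPM values are TMM-normalised counts. Replicates were counted as separate libraries, as labelled, and none was a duplicate of another: the counts within a group differed by 4.38 (Input) to 32.99 (IgG IP) times sampling noise, as a chi-square statistic per degree of freedom, which does not show whether they came from separate cultures.

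A fold change here compares a gene with the bulk of genes in the same libraries, since no external standard is used here and the absolute recovery of RNA is unknown. The total count per library was 4135463 to 8069554. The 2 genes with the most counts over all libraries took most of Input and of the IgG IP. The counts left for all other genes were 752862 and 778680 in Input, 2144182 and 2299877 in the IgG IP, and 3823470 and 3256012 in the LARP1 IP, so counting error is largest in Input. Relative to counting error, the spread between replicates was lowest there, but that measure also falls with fewer counts. The Pearson correlation of log CPM between replicates was 0.885 in Input, 0.9 in the IgG IP and 0.893 in the LARP1 IP. The Spearman correlations were 0.865, 0.886 and 0.849, so the Input replicates are not shown to be the most alike.

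The fit was tested on simulated data drawn from the means, spreads and library sizes of these libraries, with 10291 genes tested. Each gene was given the same spread in all groups, as the fit assumes. The rates below therefore do not cover groups that differ in spread. In the LARP1 IP, 200 genes were changed, all drawn from genes with a mean of at least 10 CPM over the libraries. Many tested genes do not reach that level, and the rates below do not cover them. Against the IgG IP, 97% of the 8-fold, 71.6% of the 4-fold and 8.96% of the 2-fold changes were called, with 9 unchanged genes called. Against Input, 95.5%, 61.2% and 5.97% were called, with 4 unchanged genes called. In the simulated IgG IP against Input comparison, where nothing was changed, 0 genes were called.

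Where every library of a group had no count, the fitted fold depends on the prior count, and medians and counts of folds were also taken with such genes at a bound, the fold against 3 counts over the group. The LARP1 IP libraries are shared by the comparisons with IgG and with Input. The overlap of calls was therefore set beside the overlap of independent lists and beside 20 simulated data sets with no change in any group. The alternatives tried were DESeq2 1.42.0, upper-quartile factors, total counts, no filter, a filter at 50 counts in 2 libraries, a fit of the 4 libraries of a comparison, the replicate number as a block, a test against a log2 fold change of 1 (glmTreat), and leaving out each library. Those chosen after seeing the data were leaving out the 2 genes with the most counts, thinning the IgG libraries, and DESeq2 without each library. The gene groups described by fold, level or share of counts were also chosen after seeing the data, including the limit of 10 CPM on the group over 8-fold. The tests, filter, scaling, threshold and other alternatives were chosen before the data were examined. DESeq2 left some genes without an adjusted p, so its counts against Input rest on fewer genes than edgeR's. Over all libraries these were 1046 of 10788 genes for the LARP1 IP and 8366 for the IgG IP. For the LARP1 IP they were 6949 of 11562 without Input replicate 1 and 5858 of 11621 without Input replicate 2. The most against Input were 7276 of 11373, without LARP1 replicate 2. Leaving out a library also left genes without an adjusted p against IgG, at most 5727 of 11362, without IgG replicate 1.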

Results

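The series asked which transcripts LARP1 binds in the free 40S fraction, the part of a sucrose gradient that holds small ribosomal subunits outside assembled ribosomes. LARP1 is an RNA-binding protein known for binding mRNAs that begin with a terminal oligopyrimidine motif, a class that includes the ribosomal protein mRNAs. HCT116 is a human colorectal carcinoma cell line. RNA recovered with an anti-LARP1 antibody (LARP1 IP, n = 2) was compared with RNA recovered with control rabbit IgG (IgG IP, n = 2), which measures background, and with the unselected RNA of the fraction (Input, n = 2). Library totals were 5211809 and 4135463 counts in the LARP1 IP, 7356269 and 8069554 in the IgG IP, and 6632952 and 6424655 in Input. Between 15798 and 18016 genes had at least 1 count in a library. Genes are known here only by Ensembl ID, so gene groups are described by their levels and fold changes.

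The LARP1 IP had a different composition from both controls. The 2 genes with the most counts took 88.3% ± 0.54 of Input (SD, n = 2), 71.2% ± 0.46 of the IgG IP (SD, n = 2) and 23.95% ± 3.8 of the LARP1 IP (SD, n = 2). A group of 106 genes, described below, took 1.18% ± 0.03 of Input, 2.23% ± 0.25 of the IgG IP and 41.2% ± 7.2 of the LARP1 IP (SD, n = 2 each). These genes were chosen on the same libraries, so their shares are not independent evidence of enrichment. For either share, the libraries of the LARP1 IP lay outside the range of both controls. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33.

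**Figure D1:**
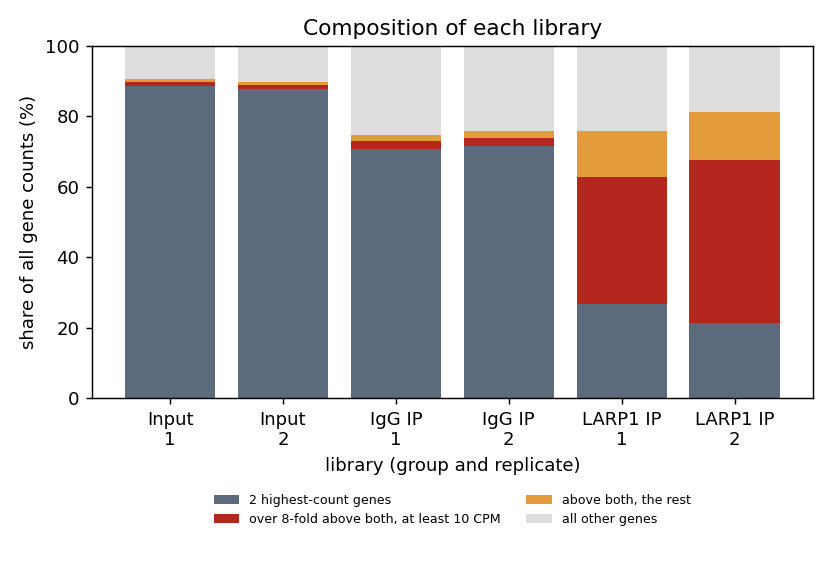
Share of all gene counts (%, vertical axis) in each of the 6 libraries (horizontal axis, by group and replicate), split into the 2 genes with the most counts, the 106 genes over 8-fold above both controls and at 10 CPM or more in the LARP1 IP, the other 365 genes above both controls, and all other genes. The 106 genes hold on average 41.2% of the LARP1 IP, 2.23% of the IgG IP and 1.18% of Input.

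Against the IgG IP, 921 of 10788 genes were higher in the LARP1 IP and 247 were lower. The higher genes had a median log2 fold change of 2.35 (quartiles 1.85 and 3.25), and 275 of them exceeded 8-fold (272 with the 11 genes that had no IgG count at their bound). The lower genes had a median of -1.82 (quartiles -2.15 and -1.67), and 14 exceeded 8-fold. Among the 10 highest genes under the naming rule, log2 fold changes ran from 4.45 to 4.74, and all 10 were also higher than Input. Among the 10 lowest they ran from -2.93 to -3.56, and 3 of the 10 were also lower than Input. Both of the 2 genes with the most counts were lower than in the IgG IP, by log2 fold changes of -1.71 ± 0.40 and -1.82 ± 0.41 (SE; edgeR adjusted p = 0.0149 and 0.0119). Their log2 fold changes lay between -1.49 and -1.91 with upper-quartile, total-count and DESeq2 scaling. Neither passed by edgeR without Input replicate 1 (log2 fold changes -1.66 and -1.78) or Input replicate 2 (-1.71 and -1.82).

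The highest gene under that rule, ENSG00000105640.12, stood at 5120 ± 1900 CPM in the LARP1 IP, 192 ± 58.6 CPM in the IgG IP and 335 ± 99.1 CPM in Input (SD, n = 2 each). Its log2 fold change was 4.74 ± 0.51 (SE) over IgG and 3.93 ± 0.49 over Input (edgeR adjusted p = 0.000179 and 0.000935). The next, ENSG00000177600.8, stood at 5070 ± 2570, 206 ± 69.4 and 470 ± 72.3 CPM in the same order, with log2 fold changes of 4.62 ± 0.52 over IgG and 3.43 ± 0.49 over Input (edgeR adjusted p = 0.000179 and 0.00112). Over Input neither passed without Input replicate 1 (log2 fold changes 4.28 and 3.60, edgeR adjusted p = 0.0648 and 0.0682) or Input replicate 2 (3.67 and 3.29, edgeR adjusted p = 0.0817 and 0.0997). The lowest gene, ENSG00000116731.22, had a log2 fold change of -3.56 ± 0.68 against IgG (edgeR adjusted p = 0.00481) and -1.26 ± 0.68 against Input (adjusted p = 0.314). The next lowest, ENSG00000090061.17, had -3.46 ± 0.74 against IgG (edgeR adjusted p = 0.00914) and 0.996 ± 0.81 against Input (adjusted p = 0.525). ENSG00000116731.22 stood at 3.69 ± 1.01 CPM in the LARP1 IP, 44.3 ± 42.8 CPM in the IgG IP and 8.95 ± 2.7 CPM in Input (SD, n = 2 each). ENSG00000090061.17 stood at 6.69 ± 3.15, 74.9 ± 80.2 and 3.41 ± 0.871 CPM in the same order. Both lower genes were far more abundant in IgG replicate 1 (807 and 1424 counts) than in IgG replicate 2 (142 and 183 counts). Without IgG replicate 1, ENSG00000090061.17 had a log2 fold change of -1.41 (edgeR adjusted p = 0.138). It also missed the threshold without Input replicate 1 (edgeR adjusted p = 0.0526) and in the fit of 4 libraries (0.0501), and with DESeq2 without IgG replicate 1 (0.279), Input replicate 1 (0.0653), Input replicate 2 (0.0629), LARP1 replicate 1 (0.0689) or LARP1 replicate 2 (0.255), with edgeR and DESeq2 adjusted p between 2.49e-10 and 0.279 over all alternatives. ENSG00000116731.22 missed it with DESeq2 without IgG replicate 1 (log2 fold change -1.91, adjusted p = 0.0744) and without LARP1 replicate 2 (-3.31, adjusted p = 0.119), in a range from 3.28e-10 to 0.119.

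The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the split into higher and lower genes depended on the scaling: total counts (median of all genes 0.145 on the log2 scale, against -0.0649 with TMM) gave 1004 higher and 75 lower, and total counts without the 2 most abundant genes (median -1.29) gave 331 higher and 4246 lower. A fit of only the 4 LARP1 IP and IgG IP libraries gave 681 higher and 80 lower of 10654 tested genes. The counts, most of all of lower genes, therefore depended on whether Input entered the fit. The number of higher genes was 579 without IgG replicate 1 and 578 without LARP1 replicate 2, and the number of lower genes was 128 and 138 without these and 65 and 89 without Input replicate 1 or 2.

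Against Input, 499 genes were higher in the LARP1 IP and 164 were lower. The higher genes had a median log2 fold change of 2.50 (quartiles 1.99 and 3.29), with 168 over 8-fold (160 with the 14 genes that had no Input count at their bound). The lower genes had a median of -2.47 (quartiles -2.93 and -2.10), with 37 over 8-fold. Under the naming rule the 10 highest ran from 4.06 to 5.97, and all 10 were also higher than the IgG IP. The 10 lowest ran from -3.56 to -4.78, and 7 of them were also lower than the IgG IP. The 2 genes with the most counts were lower than in Input by log2 fold changes of -4.16 ± 0.44 and -2.87 ± 0.42 (SE; edgeR adjusted p = 0.000935 and 0.00123), and by -2.43 and -1.17 with total counts. Neither passed by edgeR without Input replicate 1 (log2 fold changes -4.07 and -2.73) or Input replicate 2 (-4.22 and -2.98).

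With total counts in place of TMM, which moved the median of all genes to 1.75 on the log2 scale, 6566 genes were higher than Input and 27 lower, and total counts without the 2 most abundant genes moved it to -0.99 and gave 188 and 1320. With edgeR, 0 genes passed without Input replicate 1 (1872 at an unadjusted p under 0.05; DESeq2 called 355 higher and 61 lower) or without Input replicate 2 (1189; DESeq2 247 and 79), 237 were higher and 78 lower without LARP1 replicate 2, and 253 to 279 were lower without IgG replicate 1, IgG replicate 2 or LARP1 replicate 1.

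The genes of most interest in this design are those above both background and Input. There were 471 such genes, with a median log2 fold change of 2.84 over IgG and 2.53 over Input. Together they took 71.6% ± 6.6 of the LARP1 IP counts outside the 2 most abundant genes, 13.9% ± 1.3 in the IgG IP and 16.5% ± 0.82 in Input (SD, n = 2 each). They were chosen on the same libraries, so these shares are not independent evidence of enrichment. Within the 471, 106 genes were over 8-fold higher than both controls and at 10 CPM or more in the LARP1 IP. Their median fold was 16.4 over IgG and 10.8 over Input, and their median level was 2050 CPM in the LARP1 IP, 118 CPM in the IgG IP and 182 CPM in Input. These folds depend on the scaling: the median log2 fold changes of 4.03 and 3.43 became 4.18 and 5.07 with total counts, and 2.77 and 2.36, under 8-fold, with total counts without the 2 most abundant genes. A further 41 genes were over 8-fold by the fitted value but below 10 CPM, where the fold depends on few control counts. Of the 471 genes, 2 had no count in the IgG IP and 13 had none in Input, and the medians were again 2.84 and 2.53 with these genes at their bound. None of the 106 lacked counts in a control group.

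Genes below both controls numbered 61, and they included the 2 with the most counts. The remaining 59 took 38.6% ± 0.75 of the Input counts outside those 2, 29.5% ± 8.9 in the IgG IP and 3.27% ± 0.92 in the LARP1 IP (SD, n = 2 each). These genes too were chosen on the same libraries, so their shares are not independent evidence of a lower level. By edgeR, 0 genes were higher against one control and lower against the other, with 0 at an unadjusted p under 0.05 in both and 0 by DESeq2. Such opposite calls would need the IgG IP and Input to differ for the gene. Total counts gave 1004 genes above and 10 below both controls, and total counts without the 2 most abundant genes gave 178 and 1150. The 471 genes became 228 without LARP1 replicate 2 and, by edgeR, 0 without Input replicate 1 or 2, where DESeq2 gave 339 and 244. The 61 genes became 19 without LARP1 replicate 2, 114 without LARP1 replicate 1 and, by edgeR, 0 without Input replicate 1 or 2, where DESeq2 gave 37 and 36.

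**Figure D2:**
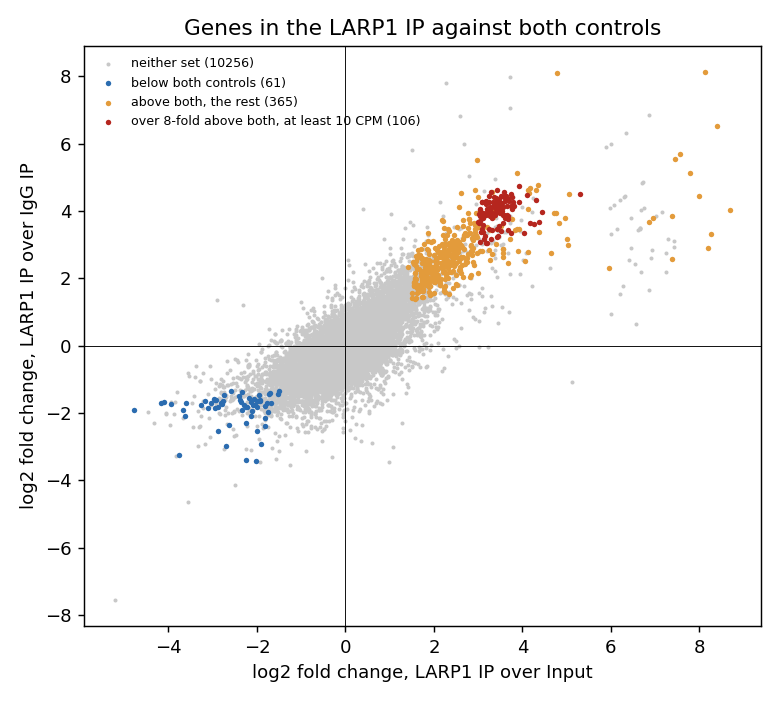
Each point is 1 of the 10788 tested genes, with its log2 fold change in the LARP1 IP over Input (horizontal axis) and over the IgG IP (vertical axis), coloured by the gene's set. The 106 genes over 8-fold above both controls and at 10 CPM or more in the LARP1 IP lie around the medians of 4.03 over IgG and 3.43 over Input.

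Independent lists of these sizes would share 42.6 higher and 3.75 lower genes, and 20 simulations with no change in any group shared 0 of either. The simulated lists hold no real effects, so they do not show how much overlap the shared LARP1 IP libraries give to lists of the observed sizes. The covariance of the log2 fold changes over genes was 1.11, against 0.172 from the shared LARP1 libraries in the simulations, with a correlation across genes of 0.81 observed and 0.47 simulated. Since the LARP1 IP has only 2 libraries and was not split, part of the overlap may come from sharing them. Of the 106 genes, 105 passed both tests with DESeq2, 106 with upper-quartile factors, 100 with total counts without the 2 most abundant genes (at the lower folds given above), and 99 without LARP1 replicate 2 (87 with DESeq2). Without either Input library 0 passed both tests with edgeR, against 96 and 99 with DESeq2, while their median log2 fold change over Input stayed at 3.52 and 3.35.

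The IgG IP was compared with Input to measure what the control serum recovers. By edgeR's test, 0 of the 10788 genes passed the adjusted threshold, and 725 genes (6.72%) had an unadjusted p under 0.05. DESeq2 called 19 genes higher and 19 lower, but gave no adjusted p to 8366 of the genes. The printed lower genes ENSG00000116731.22 and ENSG00000090061.17 had log2 fold changes of 2.3 and 4.45 here (edgeR adjusted p = 0.623 and 0.235). Both passed with DESeq2 (2.28 and 4.43, adjusted p = 0.0432 and 0.0167). The 2 genes with the most counts had log2 fold changes of -2.45 ± 0.41 and -1.05 ± 0.40 (SE; edgeR adjusted p = 0.164 and 0.734). The first of them passed with DESeq2 (log2 fold change -2.49, adjusted p = 9.01e-09). It also passed by edgeR with total counts (-0.94, adjusted p = 0.00985), without IgG replicate 2 (-2.61, 0.000748), without LARP1 replicate 1 (-2.45, 5.75e-05) and without LARP1 replicate 2 (-2.44, 1.59e-05). With total counts the second turned to 0.46 (edgeR adjusted p = 0.0235). The 106 genes over 8-fold above both controls and at 10 CPM or more had a median log2 fold change of -0.60 in the IgG IP over Input, which turned to 0.905 with total counts. With total counts, which moved the median of all genes to 1.51 on the log2 scale, 5816 genes were higher in the IgG IP and 6 lower. Without IgG replicate 2, edgeR called 41 higher and 9 lower, and without IgG replicate 1 or either LARP1 replicate it called 3 to 5 higher and 7 to 11 lower.

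**Figure D3:**
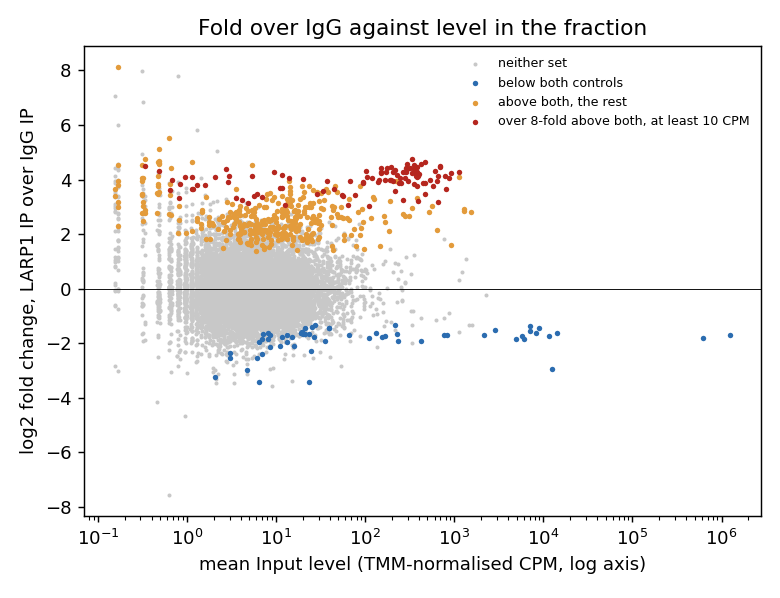
Mean Input level in TMM-normalised CPM (horizontal log axis) against the log2 fold change of the LARP1 IP over the IgG IP (vertical axis) for each tested gene, coloured by set, with 52 genes without an Input count left out. The 106 genes over 8-fold above both controls and at 10 CPM or more in the LARP1 IP have a median Input level of 182 CPM, and the 2 genes with the most counts lie at the far right, below 0.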

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

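The alternatives that left out the 2 most abundant genes, the thinning and DESeq2 without each library were chosen after seeing the data. Counts are given as higher and lower in the first-named group, with genes above and below both controls (471 and 61) last. Before the leave-one-out ranges, only counts that moved by over 1.5 times are listed, and smaller changes are left out. DESeq2 moved only the IgG IP against Input counts by that much, to 19 and 19. Total counts left 75 genes lower than IgG, gave 6566 and 27 against Input, 5816 and 6 for the IgG IP, and 1004 above and 10 below both. Without a low-count filter, 821 genes were higher than Input and the IgG IP had 56 and 17. Just inside the limit, 706 were above both and 368 lower than IgG. The filter at 50 counts gave 105 below both. Fits of 4 libraries gave 80 lower than IgG, 5 and 8 for the IgG IP, and 32 below both. glmTreat gave 422 and 22 against IgG, 198 and 45 against Input, and 192 above and 0 below both. Total counts without the 2 most abundant genes gave 331 and 4246 against IgG, 188 and 1320 against Input, 1 lower for the IgG IP, and 178 above and 1150 below both. Upper-quartile factors and TMM without the 2 genes kept these 8 counts within 1.5 times, as did thinned IgG libraries for LARP1 IP against IgG IP, the comparison they were run for; upper-quartile factors moved the median of all genes against Input from 0.0328 to -0.0987. Leaving out each library, where the lone library of a group is assumed to vary like the other groups, gave edgeR ranges of 578 to 977 higher and 65 to 307 lower against IgG, 0 to 723 and 0 to 279 against Input, 0 to 41 and 0 to 11 for the IgG IP, and 0 to 654 above and 0 to 114 below both. DESeq2 gave 411 to 744 and 59 to 163, 246 to 486 and 61 to 188, 0 to 38 and 1 to 22, and 233 to 434 and 34 to 67. Apart from construction (fewer samples, a different threshold, filter or scaling), the cause was not tested.

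The labels give the groups the same replicate numbers but no shared batch. Deviations of same-numbered libraries from their group means correlated at 0.271 (IgG IP and Input), 0.519 (IgG IP and LARP1 IP) and 0.134 (Input and LARP1 IP), a hint from the data only, since 2 libraries per group make the 2 deviations of a group mirror images. With the replicate number as a replicate block, 1526 genes were higher and 909 lower against IgG, 1083 and 551 against Input, 39 and 35 for the IgG IP, and 938 above and 287 below both; all 921, 247, 499 and 164 calls of the unblocked fit remained.

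For the 4 printed genes, 1 value changed sign with a call: ENSG00000105640.12 in the IgG IP over Input went from -0.81 to 0.70 with total counts, which moved the median of all genes in that comparison from 0.00822 to 1.51 and so restates that shift. The planned fits on protein-coding genes, the gene-length trend, pseudogene counts, the gene lists, the comparison of lists and the shares per list were not run, since the IDs could not be named. Input had the fewest counts outside the 2 most abundant genes (at most 778680) and so the largest counting error; its effect on the calls was tested only by thinning the IgG libraries.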

Other observations

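Genes above both controls were unevenly spread over the levels of the control libraries. With the tested genes divided into 5 bins of 2157 or 2158 by mean level in the IgG IP and Input, a ranking chosen after the data were seen that leaves out the LARP1 IP, 9.45% of the most abundant bin were above both controls, against 1.99% to 3.94% of the other bins. Genes below both controls were also more frequent in the most abundant bin (1.9%, against 0.0463% to 0.603% of the other bins), a pattern that more power at higher counts would give in both directions. The genes over 8-fold above both lay mostly at both ends, with 77 of 147 in the most abundant bin and 54 in the least abundant. Of the 54, 13 reached 10 CPM in the LARP1 IP. A gene with few control counts can pass the filter through the LARP1 IP libraries alone, and the control level is also what the fold divides by. The number at the low end may therefore be set partly by how genes were chosen. Of the 100 genes most abundant in the controls after the first 2, 54 were above both controls, 15 were below both and 22 passed neither test. Another 450 genes were higher than the IgG IP without passing against Input. The difference between these comparisons was not tested per gene. All 450 had a positive fitted log2 fold change over Input, with a median of 1.34 (also with 16 genes without an Input count at their bound), which choosing them on the same LARP1 IP libraries favours even without an effect (correlation of the fold changes across genes 0.47 in simulations with no change). They took 2.58% ± 0.26 of the LARP1 IP counts outside the 2 most abundant genes (SD, n = 2).

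Genes chosen in 1 replicate number were read in the other, on log2(CPM + 1) ratios. Of 148 genes over 4-fold above both controls in replicate 1 and at 10 CPM or more in the LARP1 IP, 143 (96.6%) were over 4-fold above both in replicate 2, against 12.4% of all 3131 genes at that level there. Of 388 genes chosen in replicate 2, 147 (37.9%) were over 4-fold again in replicate 1, against 4.89% of 3025 genes, and 384 were above both controls by any amount. The median log2 ratio of the 106 genes over Input was 2.79 within replicate 1 and 3.78 within replicate 2.

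The tests that left out the 2 most abundant genes before TMM and that read the 20 genes highest in Input were chosen after the data were seen. The other tests below were set before their results were seen, but the readings of the tests on the shift of the scaling and on total counts without the 2 genes were changed afterwards, as stated with each.

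The LARP1 IP had 921 genes higher and 247 lower than the IgG IP. Leaving out the 2 most abundant genes before TMM kept 75.4% of the calls as higher, so the TMM calls did not rest on these 2 genes. TMM trims genes of extreme level or ratio, so this outcome was largely set by the method and bears on no other scaling. Moving the LARP1 scaling by 0.38 on the log2 scale would equalise the calls; this exceeds 0.176, the bound set in advance against the scaling as the cause (2 times the largest difference between TMM, upper-quartile and DESeq2 medians), but all of these centre on most genes, so after the result was seen the bound was judged unable to exclude the scaling. Total counts without the 2 genes left 7.23% of the calls as higher, which met the criterion set in advance for these genes as the cause. Only after this was seen was the test judged void, because it moved the median of all genes to -1.29. Genes above both controls filled 71.6% of the remaining LARP1 IP counts. Those genes were called with TMM on the same libraries, so their share is not independent support for that judgement. The split therefore stays open to the scaling, and a selective gain of RNA in the LARP1 IP is an untested hypothesis.

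Fewer genes were higher against Input (499) than against IgG (921), a difference that leaving out 1 Input library changes, since edgeR then called 0 genes against Input (1872 and 1189 at an unadjusted p under 0.05; DESeq2 355 and 247 higher) and 676 and 681 against IgG. Those fits kept the order, which turned with total counts (1004 against IgG and 6566 against Input). It turned as well in the edgeR fit without IgG replicate 1, but not in the DESeq2 fit without that library. Thinning the IgG libraries to 765771 counts outside the 2 most abundant genes, the mean of Input, gave a median of 842.5 higher genes over 20 thinnings (range 800 to 890), above the midpoint of 710. Within the fit of 6 libraries, this argues against control depth alone as the main cause. Thinning left the Input libraries and their part in the shared spread unchanged, and it was not run in fits of 4 libraries. When each comparison was fitted on its own 4 libraries, which changed the tested genes (10654 and 9485) and the estimate of the spread together, the counts were 681 and 639. A difference in what the IgG IP and Input hold may contribute and was not separated from this.

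The 106 genes had a median Input level at percentile 98.9 of the tested genes, which the limit of 10 CPM in the LARP1 IP partly sets: for all 147 genes over 8-fold the median was 95.5 (quartiles 2.35 and 99.2), and for the 41 under the limit 1.25. If recovery rose with abundance for all genes, most abundant genes would be enriched. Of the 200 genes highest in Input after the first 2, 53.5% (exact binomial 95% interval 46.3% to 60.6%) had a log2 fold change over 1 against IgG and 76 were over 3, against 16.8% of all genes over 1, which goes with recovery rising with abundance, but 64 lay below 0 and the share fell between the bounds set in advance. Of the 20 highest, 20% (5.73% to 43.7%) exceeded 1 and 15 lay below 0, with a median of -1.48. For these 20 genes the values argue against recovery that rises up to the most abundant genes, and they leave a rise below them open. Both intervals treat genes as independent draws, which lists fixed by Input level are not. A selection of particular abundant transcripts by LARP1 is a candidate explanation, not tested here without gene names.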
